A study of Mus musculus with 2 samples.

How the data were processed

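ChIC-seq libraries were made from sorted mouse LTi cells of the C57BL/6 strain that were lineage-negative, positive for CD127 and CCR6, and negative for KLRG1, NK1.1 and NKp46. Per the labels' protocols, 500 cells per sample were fixed in 1% formaldehyde for 10 minutes, incubated with an anti-TCF-1 antibody bound to a protein A fusion of micrococcal nuclease, and digested for 3 minutes at 37 °C. The 2 samples were a Tcf7+/+ library from Peyer's patches and a Tcf7fl/fl-VavCre library from small intestinal lamina propria, 1 library per group.

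Reads were aligned with Bowtie2 2.4.2 to mm10 and islands were called with SICER 2.0, per the submitters' processing notes. The caller's window, gap and filter settings, and the handling of duplicate reads, are not given in the sources used here. Island widths were multiples of 200 bp and the smallest gap between islands was 600 bp. The table holds 19531 islands and was not filtered on its FDR, since 1997 islands have an FDR of 1. Positions are given counted from 1, after adding 1 to the start and end in the table, which count from 0.

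The read counts were deposited as whole reads per island of a peak and a control library, per the file headers, without scaling. These are 2 columns whose header names no sample, so neither was tied to a genotype, and the planned comparison of the genotypes was made only as peak against control library. The fold per island was deposited by the authors as a ratio of peak to control reads. Recomputation showed that it uses the same library scaling factor, 1.997, for all 18419 islands with at least 1 control read. For the 1112 islands without control reads a fixed value stands in for the control count, 0.203 control reads in the 33 islands of 200 bp and 0.25 in the 1079 wider ones whatever their width, so such folds are not bounds. The 0.203 reads per 200 bp were taken as the caller's expected background. Lower bounds were computed against a floor of 3 control reads per island, which takes the peak reads as known, and given beside the exact 95% lower bound, which does not. The p-value per island was deposited by the authors. It is 1 for the 1997 islands with a fold below 1. For the others it equals, within 4.77e-08, the Poisson probability of more peak reads than were counted, given the scaled control reads or the value that stands in for them, and the FDR equals that p-value times the number of islands over its mean rank within 6.08e-07.

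Gene coordinates came from a RefSeq gene table of assembly GRCm38.p6, the mm10 build, with 21887 protein-coding genes on placed nuclear chromosomes. The table gives gene starts and ends without strand or exons, and a genome sequence was not used here. This changed the design. A locus is the gene and 10 kb on either side of it instead of the upstream side alone, the promoter class became the 1 kb on either side of both gene ends, exons and introns were not told apart, and random placements fell between the outermost protein-coding genes of each chromosome, assembly gaps included. The planned tests of the TCF motif in islands and of island strength against the motif were not run, nor was the alternative locus of 5 kb around the transcription start.

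Pooled folds sum reads over islands, with exact conditional binomial (Clopper-Pearson) 95% intervals, and lists were pooled over islands with fewer than 200 peak-library reads. Shares have Clopper-Pearson 95% intervals. Each gene list was set against 10000 random lists of the same size matched on 10 steps of locus length, and its percentile counts ties by the usual mid-rank. Alternatives used 2000 random lists and gene families 1000. Fisher's exact tests, two-sided, compared the identity list with 6 marker lists over genes, and with the 13 other lists over reads outside shared islands, each family adjusted by Benjamini-Hochberg. The tests over reads were chosen after the data were seen. Genes are not replicates and share islands where they are neighbours, so these tests describe these 2 libraries. With 1 library per group there was no test between conditions.

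The following were fixed before the data were examined: the gene lists, the alternatives in the locus, thresholds, scaling and chromosomes, and the rule for named genes. That rule names 15 genes in every case (Tcf7, Il7r, Id2, Gata3, Lef1, Axin2, Ccr6, Cxcr5, Lta, Ltb, Tnfsf11, Il22, Il17a and Il23r, and 1 gene that is not reported here). It also names, per list, up to 4 members whose best island has the highest fold and the first 2 members in list order without an island. Islands are named for the 10 highest folds with at least 20 peak-library reads, the 5 lowest FDR values and the 3 largest widths, and ties with the last of the first 2 groups are named too. Best islands picked by their fold overstate it. The 14 lists are LTi and ILC3 identity, LTi effector molecules, migration and adhesion, Wnt pathway and TCF partners, T cell programme of TCF-1, survival and cell cycle, NF-kB and cytokine signalling, NK cell and ILC1 markers, ILC2 markers, B cell markers, myeloid markers, epithelial markers, liver, neuron and muscle genes, and housekeeping genes. All 217 listed genes were found in the gene table. After the data were seen, a second B cell list, AP-1 and early response genes, circadian clock genes, the MHC class II pathway and 5 gene families were added, together with the binomial test of both counts and the removal of mitochondrial and high-read islands. Ighm, Ighd and Igkc were left out of the second B cell list because the gene table does not class them as protein-coding.

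Before use, the island tests and the exact interval of a single island's fold were tested on simulated reads. The list percentiles were checked with random gene lists on the real islands, and pooled folds were not simulated. For each island, reads were drawn from the real totals with 200 islands changed by known folds. At a simulated 2-fold change the caller's test passed 25 of 50 islands and the binomial test 0 of 50, and at 8-fold they passed 50 and 14 of 50. Islands were not selected on simulated peak-library reads, and these rates depend on how many islands are changed. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.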

Results

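Lymphoid tissue inducer (LTi) cells are innate lymphoid cells that help to form lymph nodes and Peyer's patches. They were profiled by chromatin immunocleavage sequencing (ChIC-seq), in which an antibody brings micrococcal nuclease to a chromatin-bound protein and the DNA cut loose is sequenced. The antibody was raised against TCF-1, the HMG-box transcription factor encoded by Tcf7. The series holds 2 libraries of 500 fixed mouse LTi cells each. In 1 library the cells were Tcf7+/+ and came from Peyer's patches, and in the other they were Tcf7fl/fl-VavCre, a genotype that deletes Tcf7 in haematopoietic cells, and came from the lamina propria of the small intestine. Genotype and tissue differed together, and each had 1 library, so no difference between them has a replicate check.

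The deposited table lists 19531 islands, stretches of clustered reads, each with the reads of a peak library and of a control library. Its header does not say which sample is which. "Control" is the caller's word for the background library, while the abbreviation Ctrl stands in the title of the Tcf7+/+ sample. All values are therefore given for the peak and the control library, and no direction between genotypes is drawn from them. The islands held 483771 reads of the peak library and 189291 reads of the control library, and the depth of the whole libraries is unknown. Fold, p-value and FDR of an island are the authors' own values. Pooled folds divide summed peak-library reads by summed control-library reads times the caller's scaling factor of 1.997, with exact 95% intervals that cover counting error only, since reads amplified by PCR are not independent molecules.

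Reads of the peak library exceeded the scaled control library in most of the called islands, by a modest factor. Islands were selected for peak-library reads, so this excess may come in part from that selection. The 19513 nuclear islands with fewer than 200 peak-library reads had a pooled fold of 1.62 (95% interval 1.61 to 1.63), from 386196 against 119307 reads. Mitochondrial DNA went the other way, with 24610 against 25524 reads in 3 islands and a pooled fold of 0.483 (0.474 to 0.491). Pooled, the 15 nuclear islands with 200 or more peak-library reads also lay below 1, at 0.822 (0.812 to 0.832). Not all of them did singly: an island at Fosb had 230 against 88 reads and a fold of 1.31. The island with the most reads was on chromosome 2 at 98666201 to 98668000, 1034529 bp from Lrrc4c, with 28574 against 19227 reads. With these 18 islands included, the pooled fold was 1.28.

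Most islands were short and held few reads. The median width was 1400 bp (quartiles 1000 and 2000 bp), and the islands together covered 32.2 Mb. The median island had 16 peak-library reads (12 to 24) and 4 control-library reads (2 to 8), and 1112 islands had no control read. The median fold was 1.84 (quartiles 1.25 and 3.17). At an FDR of 0.05 or less the caller's test passed 12215 islands (62.5%), and at 1e-05 or less it passed 4038 (20.7%). A fold below 1 was found for 1997 islands (10.2%), for 5052 (25.9%) when the table's totals were set equal, and for 29 (0.148%) with unscaled reads. Setting the totals equal lowers every fold by 0.36 on the log2 scale, and leaving out the scaling raises it by 1.00, so the side of 1 on which a fold lies depends on the scaling. The percentiles of a list's genes with any island and of its pooled fold do not, since 1 factor applies to all islands. The calls at an FDR threshold do, and their percentiles were computed with the caller's factor alone.

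**Figure D1:**
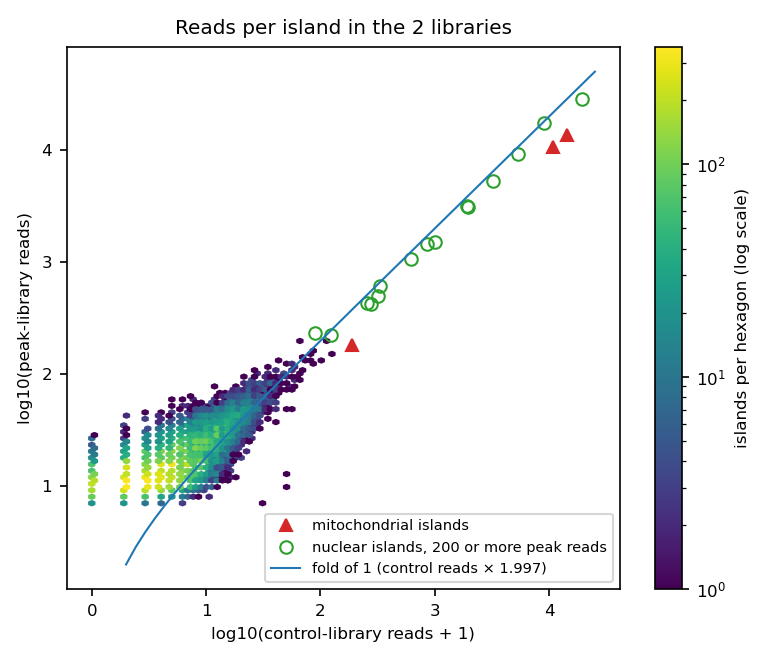
Reads per island in the peak library (vertical axis, log10 of reads) against the control library (horizontal axis, log10 of reads plus 1), with colour showing the number of islands per hexagon on a log scale. Red triangles are the 3 mitochondrial islands, green circles the 15 nuclear islands with 200 or more peak-library reads, and the line marks a fold of 1; the mitochondrial islands, pooled fold 0.483, lie below the line.

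The caller's test takes the control count of an island as known without error, and with a median of 4 control reads that error is large. An exact conditional binomial test of both counts, added after the data were seen, passed 84 islands after Benjamini-Hochberg adjustment, all of them among the 12215, and 4699 at an unadjusted p below 0.05. In simulated reads for the 19513 islands, the caller's test passed 2232 of 19313 unchanged islands (11.6%) and the binomial test passed 0.

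Tcf7, the gene deleted in the Tcf7fl/fl-VavCre cells, lies on chromosome 11 at 52246527 to 52283383 (mm10). Its body and the 10 kb on either side held 9 islands, 5 of them at an FDR of 0.05 or less, with 143 against 31 reads and a pooled fold of 2.31 (1.56 to 3.53). The island with its highest fold, at 52263401 to 52264600 inside the gene, had 12 against 1 reads, a fold of 6.01 (0.889 to 257). Exon positions were not used here, so a loss of the floxed segment could not be read from these islands and the locus does not check the genotype labels.

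Genes listed for the identity of LTi cells and the related group 3 innate lymphoid cells (ILC3) carried islands throughout. The listed genes are not all particular to these cells: Gata3 also stands in the list of the T cell programme of TCF-1. All 25 genes of the LTi and ILC3 identity list had an island within the gene or 10 kb of it, and each of the 25 had an island at an FDR of 0.05 or less, against a median of 15 and 12 genes in 10000 random lists matched on locus length. The list lay at the 100th percentile of those random lists, a percentile that the NF-kB and cytokine signalling list also reached. The identity list's 156 islands had a pooled fold of 1.91 (1.78 to 2.06), which was the 91.1th percentile for the pooled fold. Kit, the stem cell factor receptor, had 7 islands, all at an FDR of 0.05 or less, with 129 against 7 reads and a pooled fold of 9.23 (4.35 to 23.4). The island at 75622601 to 75625200 on chromosome 5, inside Kit, had 41 against 1 reads and also passed the binomial test (adjusted p = 0.00423).

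The number of islands per gene of this list ran from 1, at Ahr and Cd4, to 16, at Il1r1. Il1r1, the interleukin-1 receptor, had 16 islands, 15 of them at an FDR of 0.05 or less, where 0.825 would be placed in a locus of its length by an even spread, and a pooled fold of 3.20 (2.34 to 4.45). Rora, which encodes a nuclear receptor, had 15 islands and a pooled fold of 3.27 (2.48 to 4.37). Batf, an AP-1 family factor, stood at 2.00 (1.24 to 3.36) over 5 islands. Il23r, the interleukin-23 receptor, had 7 islands and a pooled fold of 1.81 (1.27 to 2.62). Id2, an inhibitor of E proteins, had 2 islands with 113 against 31 reads, a pooled fold of 1.83 (1.22 to 2.81). Il7r, which encodes CD127, had 5 islands and a pooled fold of 1.41 (1.07 to 1.89). Gata3 had 3 islands and a pooled fold of 1.62 with an interval of 0.926 to 2.98 that includes 1.

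**Figure D2:**
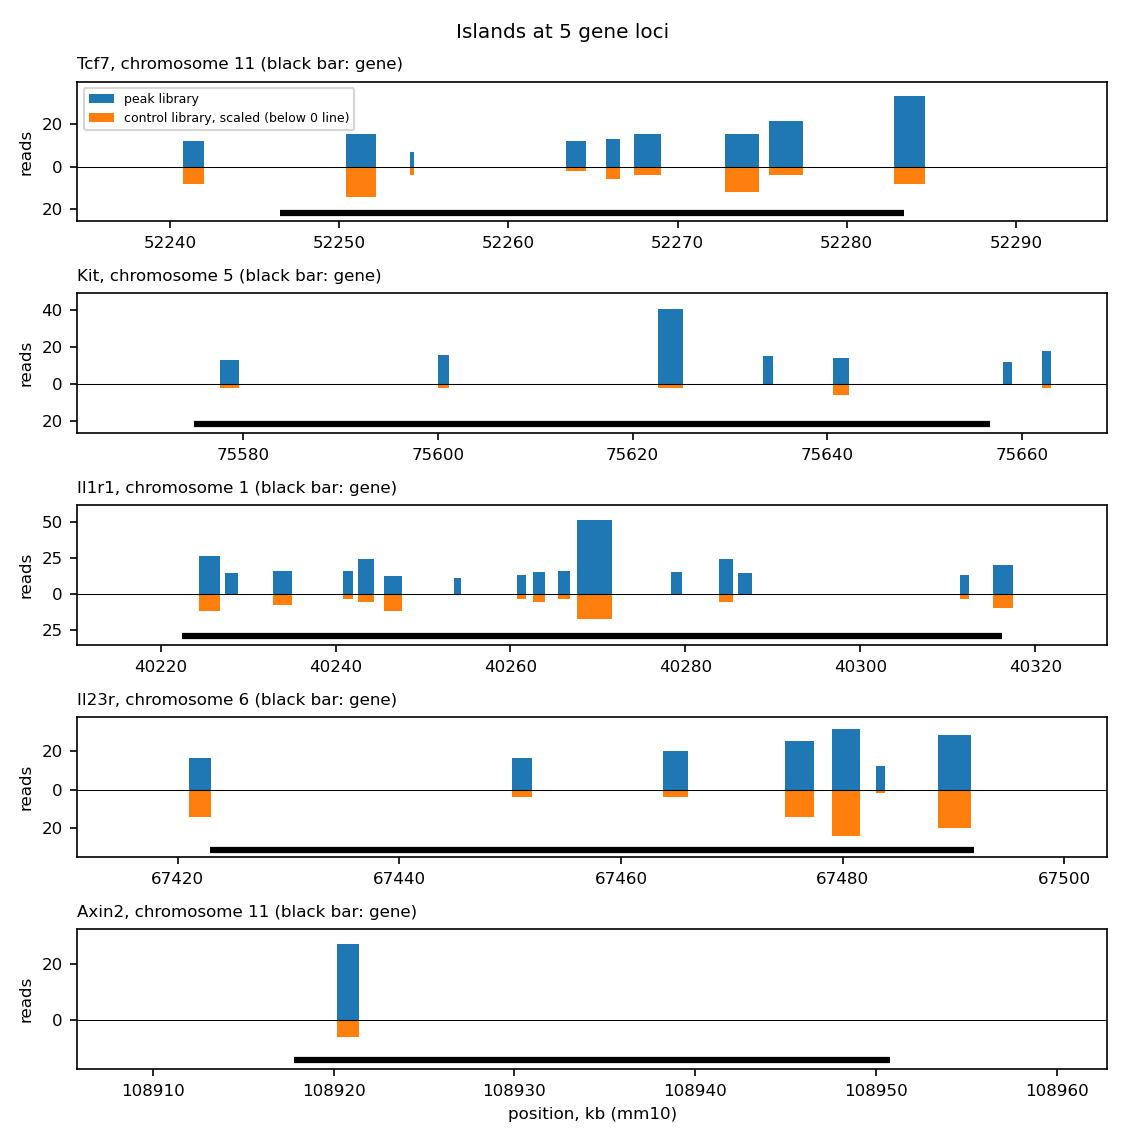
Islands at Tcf7, Kit, Il1r1, Il23r and Axin2, with position in kb (mm10) on the horizontal axis. Bars show reads per island of the peak library upward and of the control library, multiplied by the scaling factor, downward; bar width is the island's width and the black bar is the gene. Kit has 7 islands with 129 against 7 unscaled reads, while Il23r has 148 against 41.

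Of the 14 genes for LTi effector molecules, the cytokines and TNF family ligands by which these cells act, 12 had an island, the 99.0th percentile of random lists, and all 12 had an island at an FDR of 0.05 or less. Islands with at least 20 peak-library reads lay at 6 of the 14 genes, the 74.5th percentile, and with 50 kb on either side 13 genes had an island, the 97.2th percentile. The pooled fold was 2.01 (1.67 to 2.44). Tnfsf11, which encodes RANKL, had 3 islands and a pooled fold of 3.09 (1.29 to 8.95). Il22 had 1 island over its end, at 118204201 to 118205000 on chromosome 10, with 11 against 1 reads and a fold of 5.51 (0.801 to 237). Il17a had 1 island 5905 bp outside the gene, with 16 against 0 reads, at least 2.67-fold higher when set against a floor of 3 control reads; the exact 95% lower bound, which also covers the error of the 16 reads, was 1.93. Il17f had 2 islands and a pooled fold of 3.76 (1.32 to 14.7), and Tnfsf4, the OX40 ligand gene, had 1 island with 15 against 1 reads. Lta and Ltb, which encode the subunits of lymphotoxin, are neighbours on chromosome 17 and share islands: 4 lay within 10 kb of Lta, with a pooled fold of 1.5 (1.15 to 1.99), and 6 within 10 kb of Ltb, with 1.62 (1.25 to 2.14). Tnf, also in the list, had 6 islands, among them all 4 of Lta. These neighbours do not count independently in the list's percentile, since random lists were matched on locus length alone. Tnfsf13b and Vegfa had no island.

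In the list of the Wnt pathway and TCF partners, 21 of 25 genes had an island, at the 99.5th percentile, and 18 had an island at an FDR of 0.05 or less. The pooled fold of 1.69 (1.52 to 1.88) was close to the 1.62 of nuclear islands with fewer than 200 peak-library reads. Axin2, a feedback inhibitor of Wnt signalling that TCF factors are known to bind, had 1 island inside the gene, at 108920201 to 108921400 on chromosome 11, with 27 against 3 reads and a fold of 4.51 (1.39 to 23.2). Lef1, which encodes the closest relative of TCF-1, had 6 islands and a pooled fold of 1.87 (1.2 to 3.00). Znrf3, a ubiquitin ligase that removes Wnt receptors, had 13 islands and 2.09 (1.57 to 2.81). Apc had 4 islands with 1.90 (1.15 to 3.29), and Lgr5 had 1 island with 18 against 1 reads, a fold of 9.01 (1.42 to 376). Gsk3b had 4 islands but a pooled fold of 0.981 (0.688 to 1.41). Ccnd1 and Dkk1 had no island.

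Of the 22 genes listed for the T cell programme of TCF-1, 17 had an island, the 94.1th percentile. The central 95% of random lists spanned 9 to 18 genes. Whether TCF-1 controls each listed gene was not tested. The pooled fold was 1.5 (1.33 to 1.70). Cd5 had 2 islands with 21 against 3 reads, a pooled fold of 3.51 (1.05 to 18.4), and Cd28 had 2 with a pooled fold of 1.47 (0.783 to 2.91). The neighbouring Rag1 and Rag2, which encode the V(D)J recombinase, shared 1 island with 15 against 1 reads. Cd3d and Cd3g, also neighbours in this list, share islands too. Bcl11b and Cd6 had no island. With gene bodies alone, 12 of the 22 genes had an island, the 61.9th percentile, and with islands at or above the median fold 14 had one, the 99.3th percentile.

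Of 18 migration and adhesion genes, 17 had an island, the 99.9th percentile, and 12 had an island at an FDR of 0.05 or less. The pooled fold was 1.62 (1.45 to 1.81). The hyaluronan receptor gene Cd44 had 7 islands and a pooled fold of 2.49 (1.66 to 3.85), and Itgae, an integrin gene, had 4 with 2.04 (1.1 to 4.08). The chemokine receptor gene Ccr6, whose product was used in the sort, had 5 islands and 1.65 (1.03 to 2.77). Cxcr5 had 7 islands and 1.49 (1.04 to 2.18), whereas Cxcr4 had 2 islands and 1.2 (0.776 to 1.88). Ccr9 had no island.

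Survival, signalling and housekeeping genes often had islands. In the survival and cell cycle list 14 of 16 genes had an island, the 99.1th percentile, and 10 had an island at an FDR of 0.05 or less, the 92.8th percentile. With islands at or above the median fold, 8 genes had one, the 85.4th percentile. The pooled fold of 1.24 (1.13 to 1.38) lay at the 4.01th percentile and was 0.972 with equal totals. Bcl2 had 19 islands and a pooled fold of 1.37 (1.11 to 1.71), Bcl2l1 had 4 with 1.82 (1.12 to 3.07), and Mcl1 and Cdkn1b stood at 1.12 (0.878 to 1.43) and 1.11 (0.775 to 1.62). Bcl2a1a and Mki67 had no island. All 18 genes of the NF-kB and cytokine signalling list had an island and 17 had one at an FDR of 0.05 or less, with a pooled fold of 1.49 (1.35 to 1.65) close to the random median of 1.53. Jak1 stood at 2.18 (1.52 to 3.21) over 9 islands, Nfkb1 at 1.94 (1.37 to 2.81) over 8, Stat5b at 1.75 (1.30 to 2.38) over 12, and Relb at 1.40 (0.914 to 2.20) over 4. Stat5a, in the same list, shares islands with both Stat5b and Stat3, so these neighbours do not count independently. Of 12 housekeeping genes 11 had an island, the 99.8th percentile, with a pooled fold of 1.42 (1.24 to 1.62), and 7 had an island at an FDR of 0.05 or less, the 93.2th percentile. With 50 kb on either side 11 had an island, the 96.3th percentile, and with islands at or above the median fold 6 had one, the 92.8th. Actb had 5 islands and 1.66 (1.14 to 2.47), Rpl13a had 5 and 1.40 (1.02 to 1.94), Eef1a1 had 3 and 1.74 (0.963 to 3.32), B2m had 4 and 1.45 (0.861 to 2.55), and Hprt on chromosome X had none. Reads in the identity list were shifted further towards the peak library than reads in 5 of the 13 other lists, by Fisher's exact test on reads, two-sided: the survival (adjusted p = 1.23e-10), NF-kB and housekeeping (0.000515 each), T cell programme (0.00355) and migration (0.0424) lists. Among the 8 lists that did not pass, with adjusted p of 0.119 or more, were the list of NK cells and group 1 innate lymphoid cells (ILC1), that of group 2 innate lymphoid cells (ILC2) and the B cell list, whose pooled folds of 1.91, 1.89 and 1.88 lay near the identity list's 1.91. The test takes single reads within these 2 libraries as its units. Its p-values leave out replicate error and the spread between genes, such as Kit at 9.23 and Cd83 at 1.25 within the identity list. The lists were not matched on where their islands lie relative to gene ends. Among random lists, the identity list's pooled fold lay at the 91.1th percentile.

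**Figure D3:**
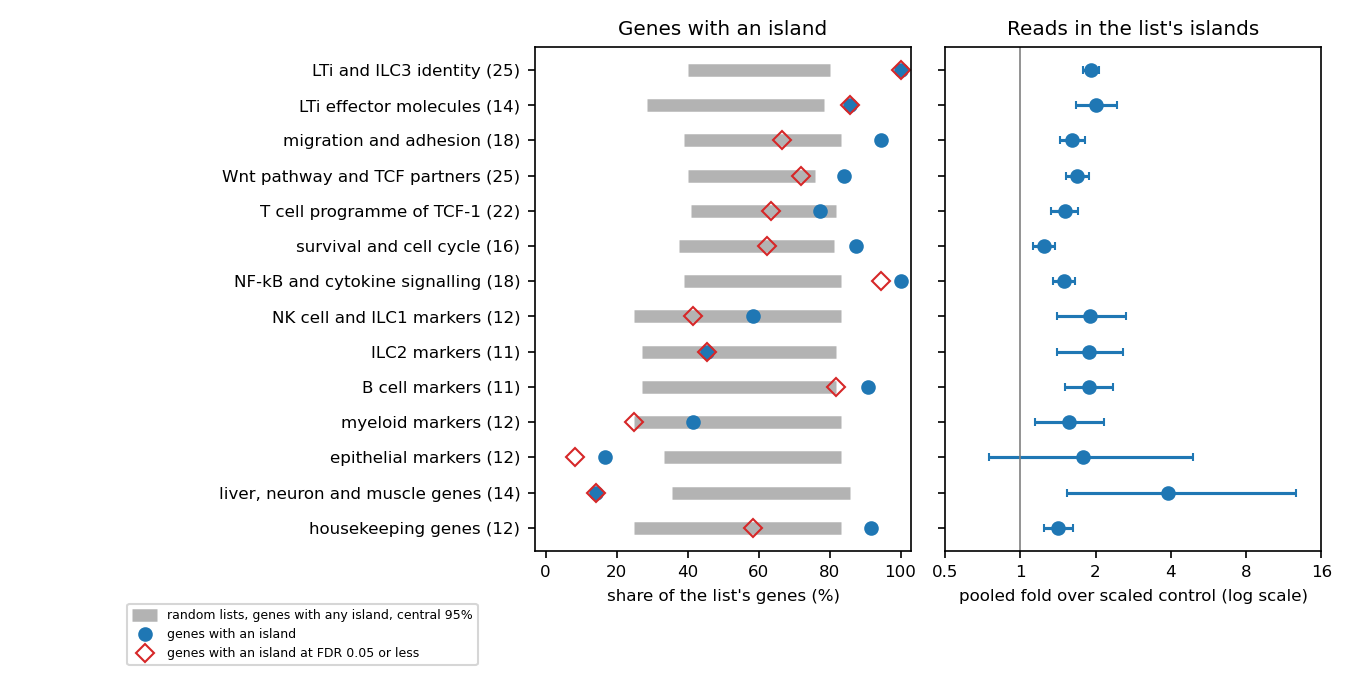
Left, share of the genes of each list with any island (blue points) and with an island at an FDR of 0.05 or less (red diamonds), in percent, with the number of genes in brackets; grey bars span the central 95% of 10000 random lists for any island. Right, pooled fold of each list's islands on a log scale with exact 95% intervals; the LTi and ILC3 identity list stands at 100% and 1.91.

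Marker genes of epithelial cells and of liver, neuron and muscle had fewer islands than random lists, while the myeloid, the ILC2 and the NK cell and ILC1 list lay inside the central 95% of random lists. The epithelial list had islands at 2 of 12 genes, the 0.095th percentile, and the liver, neuron and muscle list at 2 of 14, the 0.05th percentile. The pooled fold of the 2 islands in each list was 1.79 (0.752 to 4.90) and 3.91 (1.54 to 12.7), the latter the 99.98th percentile and the highest of the 14 lists. With 50 kb on either side these became 7 genes, the 12.2th percentile, and 6 genes, the 1.38th. At an FDR of 1e-05 or less, where the random medians were 2 genes each, they were 0 genes, the 5.35th percentile, and 1 gene, the 22.8th. The epithelial islands lay at Cdh1 (14 against 3 reads) and Krt8 (11 against 4), with none at Epcam or Vil1. The muscle genes Ckm, with 27 against 2 reads and a fold of 6.76 (1.70 to 58.7), and Myod1, with 12 against 3, had the other list's islands, and Alb and Apoa1 had none. Myeloid markers had islands at 5 of 12 genes (19.6th percentile, pooled fold 1.57), among them Spi1 with 20 against 2 reads, Cd14, Fcgr3 and Cebpb, but not Csf1r or Lyz2. ILC2 markers had islands at 5 of 11 genes (18.6th percentile, pooled fold 1.89), and at 2 with gene bodies alone, the 2.23th percentile. Il1rl1, which lies near Il1r1 on chromosome 1, had 4 islands and a pooled fold of 2.5 (1.48 to 4.50). Hpgds, Ptgdr2 and Arg1 had 2 islands each, and Il13 and Il5 had none. NK cell and ILC1 markers had islands at 7 of 12 genes (51.7th percentile, pooled fold 1.91). The neighbours Klrd1 and Klrk1, both counted among the 7, shared 1 island with 10 against 4 reads. Prf1, the perforin gene, had 21 against 1 reads in 2 islands, Itga2 had 32 against 5, and Klrb1c had 76 against 23, while Ccl5 had 1 island with 16 against 5 reads. Ncr1 and Tbx21 had none.

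Of the 11 B cell markers 10 had an island, the 98.8th percentile, with a pooled fold of 1.88 (1.51 to 2.35). With gene bodies alone 5 had one, the 42.3th percentile, with 50 kb on either side 10, the 93.1th, and with islands of at least 20 peak-library reads 6, the 90.8th. The B cell list was not tested against the other marker lists of outside cell types. Blk, a Src family kinase of B cells, had 4 islands, all at an FDR of 0.05 or less, with 76 against 7 reads and a pooled fold of 5.44 (2.51 to 14.0). Pax5 had 3 islands with 1.78 (1.01 to 3.33), Ebf1 had 5 with 1.65 (0.997 to 2.82), Cd79b had 1 with 11 against 1 reads, and Bank1 had none. Against the identity list, fewer genes had an island in the NK cell and ILC1 list (two-sided Fisher's exact test over genes, adjusted for 6 lists, p = 0.00218), the ILC2 list (p = 0.000356), the myeloid list (p = 0.000154), the epithelial list (p = 5.68e-07) and the liver, neuron and muscle list (p = 1.40e-07). The B cell list did not pass this exact test (adjusted p = 0.306), and with gene bodies alone it did (adjusted p = 0.00142). With 50 kb on either side the NK cell and ILC1 list no longer passed the exact test (adjusted p = 0.119). Over all 21887 protein-coding genes, 11974 (54.7%) had an island and 8821 (40.3%) had an island at an FDR of 0.05 or less.

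Islands were concentrated at the ends of protein-coding genes. Of 19528 nuclear islands, 6995 (35.8%, exact binomial 95% interval 35.1 to 36.5) had their midpoint within 1 kb of a gene end, against 3.22% (range 2.94 to 3.60) in 100 random placements. A further 39.9% lay inside genes, against 39.2%, and 24.3% lay between genes, against 57.6%. Among nuclear islands with fewer than 200 peak-library reads, the gene-end islands had more reads in both libraries but a lower fold. Their pooled fold was 1.45 (1.43 to 1.46), against 1.76 (1.74 to 1.78) inside genes and 1.79 (1.77 to 1.82) between genes. Control-library reads were denser there too, at 4.61 times the caller's background, against 3.06 times inside genes and 3.18 times between genes. This limit kept all 6995 gene-end islands and 4738 of 4750 islands between genes. Left out between genes was, among others, the chromosome 2 island with 28574 against 19227 reads. With that island included, the pooled fold between genes falls below that at gene ends, so the order of the classes applies only under this limit. Of all nuclear islands at gene ends, 54.0% had an FDR of 0.05 or less, against 67.0% inside genes and 67.8% between genes. Among nuclear islands with a fold at or above the median, 26.8% lay at gene ends.

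The pooled fold also depended on how many reads an island held. It was 2.09 (2.05 to 2.14) for islands with 7 to 11 peak-library reads and 1.28 (1.26 to 1.31) for the 547 nuclear islands with at least 50 and fewer than 200. Within each step below 50 reads the gene-end islands had the lowest pooled fold of the location classes, as at 24 to 49 reads, where they stood at 1.43 (1.41 to 1.45) against 1.59 (1.56 to 1.62) inside genes and 1.61 (1.57 to 1.65) between genes. From 50 reads up, gene-end islands stood at 1.25 (1.22 to 1.29), below the 1.34 (1.30 to 1.39) inside genes, while their interval overlapped that of islands between genes (1.21 to 1.32).

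**Figure D4:**
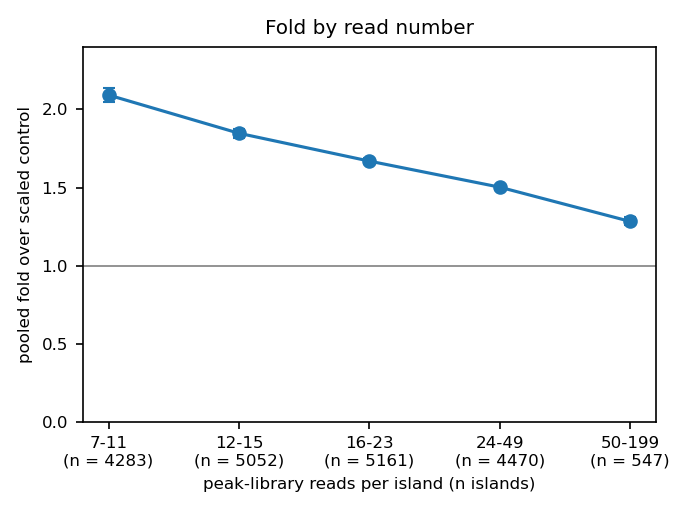
Pooled fold of nuclear islands, with exact 95% intervals, by the number of peak-library reads in the island. The fold is 2.09 in the step with the fewest reads and 1.28 in the step with the most.

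Sex chromosomes held few islands. Chromosome X had 254, which is 26.3 per 100 protein-coding genes, against 63.9 on chromosome 7 and 114 on chromosome 11, the lowest and highest of the autosomes. Its pooled fold was 1.47 (1.39 to 1.56). Chromosome Y had 4 islands.

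The 12 islands with the highest fold among those with at least 20 peak-library reads, 10 and the ties with the last of them, all had 0 control reads. Their 24 to 28 peak-library reads were at least 4.01- to 4.67-fold higher against the floor of 3 control reads, and the exact 95% lower bounds, which also cover the error of the peak-library reads, were 3.01 to 3.56. The highest lay on chromosome 9 at 52258801 to 52260600, 90.1 kb from Zc3h12c, which encodes a regnase-family RNA-binding protein. The others overlapped Tmtc4, Zmat4, Gm39469, Smyd2 and Mfsd9, or lay 16.8 kb from Ermard, 194 kb from Inhba, 17.8 kb from Scara5, 34.2 kb from Ccny, 5050 bp from Cpn1 and 12.2 kb from Lrrc28. The lowest FDR, 2.43e-36, was that of the island near Zc3h12c. It was followed at 3.26e-36 by the Kit island and an island over Ackr3, a scavenging chemokine receptor gene, at 90202201 to 90205400 on chromosome 1 with 41 against 1 reads. The islands at Tmtc4, Zmat4, Ermard and Inhba tied at 2.56e-35. The 3 widest islands had folds below 1. They lay on chromosome 9 at 3000001 to 3038400, with 17272 against 8987 reads and a fold of 0.962 (0.938 to 0.987), on chromosome Y at 90797201 to 90814000, with 0.847 (0.724 to 0.993), and on chromosome 11 at 3184201 to 3200000 over Sfi1, with 0.927 (0.809 to 1.06).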

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

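The binomial test of both counts, the calculations with and without mitochondrial and high-read islands, the location of islands at an FDR of 0.05 or less, and the lists restricted to such islands or to islands with at least 20 peak-library reads were chosen after the data were seen. The 19531 islands became 4038 at an FDR of 1e-05 or less and 10012 at or above the median fold. The 12215 islands passing an FDR of 0.05 became 18998 without scaling, 8553 with equal totals, 4293 with at least 20 peak-library reads and 84 with the binomial test. The pooled fold of 1.62 was 1.27 with equal totals and 1.28 with mitochondrial and high-read islands. It was 3.24 unscaled, 4.68 at an FDR of 1e-05 or less and 1.48 with at least 20 reads, settings that drop the factor or pick islands on peak-library reads and so do not test whether it exceeds 1. The share at gene ends, 35.8%, was 45.5% within 2.5 kb (random 7.42%), 42.1% by any overlap (random 5.59%), 26.8% at or above the median fold and 30.9% at an FDR of 0.05 or less. Wider windows and fewer islands follow from how these settings are built; for the others the cause was not tested.

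Lists above the 97.5th percentile of random lists numbered 8, and 5 with 50 kb on either side. The identity, migration, Wnt and NF-kB lists, 4 of the 8, lay above it in all 7 settings; the effector, survival, B cell and housekeeping lists did not. That setting raised the NK cell and ILC1 list's adjusted p against the identity list to 0.119, while the B cell list's fell to 0.00142 with gene bodies alone and 0.0180 with at least 20 reads (exact tests). The identity list kept at least the 99.975th percentile over 7 settings, with 16 genes at the fewest. Of 98 counts of list genes under these settings, 60 stayed within 1.5 times the reported count and 38 moved, 34 of them lower. Equal totals put pooled folds under 1.28 below 1, such as the survival list's at 0.972. The TCF motif tests, the motif against island strength and the locus of 5 kb around the transcription start were not run, since sequence and strand were not used here. No paired analysis was possible because each group had 1 library. Depth limits single islands: the binomial test passed none with fewer than 21 peak-library reads.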

Other observations

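The gene groups, loci and islands in the next paragraphs were chosen after the data were seen, as were the tests of the scaling factor, of islands of repeated sequence, of islands with few reads and of gene bodies alone. Immediate early genes had islands at all 12 members of the list of AP-1 and early response genes, the 100th percentile of random lists. Their reads were split between the libraries: the pooled fold was 1.23 (1.12 to 1.35), or 0.960 with equal totals. Fosb stood at 1.42 (1.15 to 1.77) and Zfp36, which encodes an mRNA decay factor, at 0.966 (0.767 to 1.22). The value for Fosb includes its island of 230 against 88 reads, which the list's pooled fold leaves out. The MHC class II pathway had islands at 8 of 8 genes, the 99.3th percentile of random lists. Its pooled fold was 1.03 (0.896 to 1.19), the 1.71th percentile for the pooled fold, and H2-Ab1 had 73 against 53 reads. All 10 circadian clock genes had an island, the 99.6th percentile, with a pooled fold of 1.46 (1.28 to 1.66). Cry2, a repressor of the clock, had 1 island with 48 against 6 reads, a fold of 4.01 (1.71 to 11.5), and Arntl had 6 islands and a pooled fold of 1.94 (1.24 to 3.15).

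Sensory receptor families had few islands: 29 of 1110 olfactory receptor genes (2.61%) and 6 of 353 vomeronasal receptor genes (1.70%). The medians in random lists, matched on locus length alone, were 18.6% and 33.1%. Neither expression of these families nor how well reads map to them was examined. Cytosolic ribosomal protein genes had islands at 77 of 83, the 100th percentile against a random median of 38, with a pooled fold of 1.33 (1.25 to 1.43). The Hox clusters had islands at 29 of 39 genes, and their 21 islands had a pooled fold of 2.75 (2.06 to 3.74), or 2.15 with equal totals. Interleukin receptor genes had islands at 21 of 31, the 68.1th percentile, with a pooled fold of 1.83 (1.64 to 2.04). Loci with many islands included Mbnl1 and Ankrd11 with 24 each, where an even spread over their length gives 1.28 and 1.30, Ppp1r16b with 18 against 0.867 and Il1r1 with 16. Shorter loci such as Gimap7 and Hjurp had more islands for their length, 37.1 and 32.0 times an even spread, but 0 of the 7 at Gimap7 and 3 of the 9 at Hjurp had an FDR of 0.05 or less, against 11 of 24 at Mbnl1, 14 of 24 at Ankrd11 and 12 of 18 at Ppp1r16b. Beside Kit and Ackr3, the lowest adjusted p of the binomial test were at an island over Ctdspl2 and Mageb3 (61 against 5 reads), an island in Smad3 (59 against 4), and an island 10.7 kb from Il1r1 (45 against 2).

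A pooled fold of 1.62 over islands that were selected for peak-library reads may come in part from that selection. Islands with few reads did have the higher fold, 2.09 at 7 to 11 reads, which is consistent with chance clusters raising it there. Islands with at least 50 and fewer than 200 reads still stood at 1.28 (1.26 to 1.31). They cannot decide whether selection is the whole cause, since they may join several 200 bp windows, each picked for its peak-library reads. Their fold also rests on the caller's scaling. It is an estimated 1.27 when mitochondrial and high-read islands are taken out of the factor, with library totals inferred from the caller's background. With equal totals, which absorb any shared excess by construction, it is 1.00 (0.983 to 1.02). A single wrong scaling factor would shift repeated sequence too. The median fold of the 9 nuclear islands with 500 or more control reads was 0.822, while the mitochondrial islands pooled to 0.483. These regions share no common baseline, so they cannot decide whether the factor fits the other islands. Genotype and tissue stay open and untested, since neither library could be tied to a sample.

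Control-library reads were also concentrated at the islands. A few islands of repeated sequence do not account for this, because the median nuclear island with fewer than 200 peak-library reads had 3.11 times the caller's background and 86.1% of them lay above it. Cleavage of accessible chromatin at gene ends in both libraries is a candidate explanation. Among nuclear islands with fewer than 200 peak-library reads, control density there was 1.49 times (1.47 to 1.5) that of the other islands. Those other 12518 islands held 63524 control reads, and the 15 nuclear islands left out held 44460. With these 15 included, control density at the other islands exceeds that at gene ends, so the ratio applies only under this limit. This test does not separate open chromatin from binding retained in the control library, and no biological explanation was tested.

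The B cell list had islands at 10 of 11 genes, the 98.8th percentile of random lists. Islands near these genes rather than in them may carry it: with gene bodies alone 5 of 11 genes had an island, the 42.3th percentile of random lists, a result that does not tell regulatory sequence of the B cell genes from parts of their neighbours. DNA of B cells among the sorted cells, which the lineage-negative gate is meant to remove, stays open. The second B cell list had islands at 6 of 11 genes, the 42.8th percentile, but its interval of 23.4% to 83.3% is too wide to decide. At genes of the MHC class II pathway, the pooled fold was 1.65 (1.07 to 2.61) at Cd74, 0.690 (0.478 to 1.00) at H2-Ab1 and 0.964 (0.710 to 1.32) at H2-Eb1. These genes do not test for B cell DNA, since LTi cells may express them too. Folds also do not show whether B cell DNA was in both libraries. Which of these genes LTi cells express was not measured here.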
